A study of Mus musculus with 18 samples.

How the data were processed

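Single ectoplacental cones were dissected at 6.5 days post-coitus and sexed from a second elution of their RNA, per the labels' protocols. Libraries came from a low-input, strand-specific total RNA kit after ribosomal RNA depletion, from samples with an RNA integrity number above 7. The deposited count table holds whole-number read counts per gene symbol for 18 libraries and 32655 genes, with no normalization. Per the submitters' processing notes, the tools were STAR 2.5.0c, SAMtools, featureCounts and edgeR, with the genome build mm10. The counting strand, the gene annotation and the filters on reads are not given in the sources used here, so reads shared between near-identical genes, or between a gene and its antisense partner, could be split or dropped in ways that are unknown. The deposited normalized table holds a signal that equals the counts times 1 constant per library, to within rounding. That constant matched the one that gives CPM from the product of library total and edgeR's TMM factor on the unfiltered table, and columns summed to between 0.912 and 1.09 M (mega). It was used only as an alternative input. All sample columns of both tables were used.

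Levels, fold changes and tests were computed here from the deposited counts. Genes were kept with edgeR's filterByExpr by group, which left 18795 genes and removed 13860, and libraries were scaled by TMM. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with 1 mean per group over all 18 libraries, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. A common fit was used because groups of 4 and 5 give few degrees of freedom. Standard errors were derived from the fold change and the F statistic. There were 6 comparisons: diet in males, diet in females, diet averaged over sex, the interaction of diet and sex, sex in control embryos and sex in obese embryos. Fold changes for diet are obese over control, and those for sex are female over male. Replicate numbers in the labels were not used as a block in the main test.

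Before the data were examined, 39 gene lists were fixed: 4 of trophoblast types, 8 of other cell types that a dissected cone could hold, 22 of pathways, 2 of RNA quality and 3 of sex-linked genes. The list of mitochondrial mRNAs had no gene in the table and is not analysed here, and 38 lists were tested. Lists were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, a preset correlation between genes of 0.01 and adjustment over the lists of a comparison, and again with an estimated correlation. Of 39 list results past the threshold with the preset value, 2 kept it with an estimated correlation, both of them Y-linked genes. The main design, the alternatives, the lists and the rule for named genes were also fixed at that stage. The rule named up to 10 genes higher and 10 lower with the largest fold change among those past the threshold with a mean of at least 1 CPM, leaving out predicted gene models. Where fewer than 10 genes passed, the 10 genes with the smallest p were named with values and no call. Y-linked genes, Xist and Tsix were named in the sex comparisons, and up to 4 members with the smallest p in each list.

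The tests were tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 genes changed by known folds. In the simulated diet effect in males (17974 genes), 10% of the genes changed 1.5-fold were recovered, 40% of those changed 2-fold, 80% at 4-fold and 90% at 8-fold, with 2 calls among the 17774 unchanged genes. In females (18051 genes) recovery was 18%, 50%, 80% and 88%, with 7 false calls. In the average of both sexes (18044 genes) it was 50%, 66%, 92% and 92%, with 5 false calls. In simulated data without correlation between genes, camera gave an unadjusted p below 0.05 for 1 to 2 of 100 unchanged lists.

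Replicates of a group were compared with a chi-square test of their counts, and the closest pair differed by a chi-square of 15.6 per gene, so no library was treated as a copy of another. Gene positions are from GENCODE M21 on the same build: of 32655 symbols, 31271 matched 1 gene record, 56 matched several and 1328 matched none. GC content and transcript length were found for 96.8% of the genes tested.

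The alternatives fixed beforehand were DESeq2 size factors, library size alone, no filter, a filter of at least 1 CPM in 4 libraries, a robust fit, the replicate number as a block, an adjusted p of 0.1, the DESeq2 1.42.0 Wald test, limma voom with quality weights, limma-trend on log2 of the normalized table plus 1, a fit of the compared groups alone, and leaving out each library in turn. After seeing the data, fits without HFD.male 2 and HFD.female 3, with a decidual score as a covariate, and with GC and length trends removed were added. Python 3.11.15 with SciPy 1.17.1 ran the exact permutation tests of correlations.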

Results

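The ectoplacental cone is the trophoblast tissue at the mesometrial pole of the early post-implantation mouse embryo, from which much of the placenta later forms. Total RNA was sequenced from single cones at 6.5 days post-coitus, with 1 library per cone. The dams were C57BL/6 mice of 20 weeks that had eaten either a control diet or a diet with 60% of its energy as fat from 4 weeks of age, and they were mated with control males. The 18 libraries fell into 4 groups by maternal diet and embryo sex: 4 males and 5 females from control dams, and 4 males and 5 females from obese dams, here called control and obese for short. The library names used below give the diet as Control or HFD (high-fat diet), the sex and the replicate number. Library totals ran from 8.27 M (mega) counts in HFD.female 3 to 54.3 M in Control.female 3, with a median of 18.7 M. A single gene model, Gm26917, a long noncoding RNA model on chromosome 17, took from 8.48% of the counts (Control.male 2) to 14.25% (HFD.female 4). Levels are given as CPM, the read count scaled for library total and TMM factor, as mean ± SD over the embryos of a group. The labels name no dam, litter or batch, so p-values measure the spread between embryos, some of which may be littermates.

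The first check was whether the RNA matched the sex given for each embryo. The embryos were sexed from their own RNA, so a match was largely fixed in advance. The check bears mainly on exchanged or mixed libraries. The Y-linked genes summed to between 102.2 CPM (HFD.male 2) and 187.4 CPM (Control.male 1) in the 8 male libraries, and to at most 5.34 CPM in the 10 female libraries (HFD.female 3). Xist, the X-linked noncoding RNA that coats the inactive X chromosome, lay between 849.5 CPM (Control.female 5) and 1845 CPM (HFD.female 3) in females and between 22.3 and 75.2 CPM in 7 males. In the eighth male library, HFD.male 2, Xist stood at 353.5 CPM. That library also had the highest level of Malat1, an abundant nuclear noncoding RNA, at 15015 CPM against at most 5628 CPM elsewhere, and the lowest level of the yolk sac apolipoprotein gene Apob, at 145.5 CPM against at least 1640 CPM. No female library had more Y-linked RNA than any male library.

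**Figure D1:**
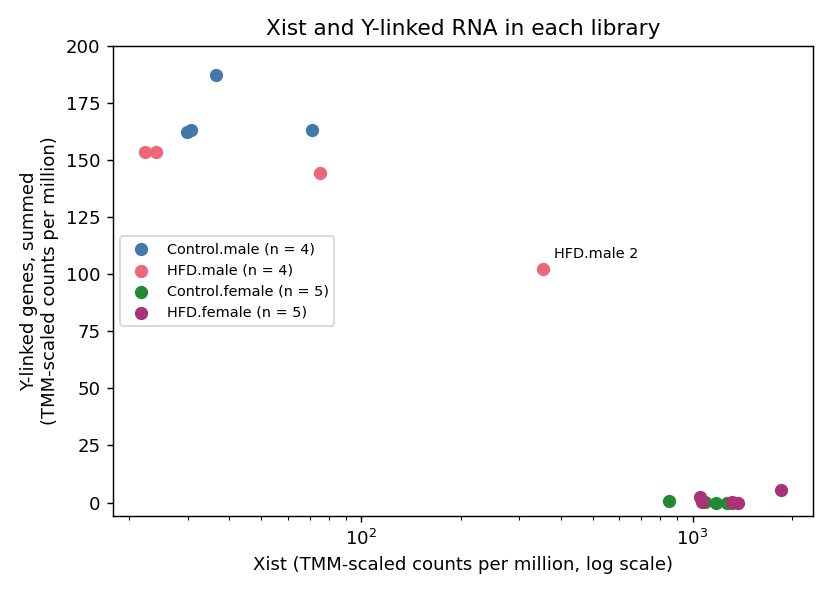
Xist (horizontal axis, TMM-scaled CPM, log scale) against the summed Y-linked genes (vertical axis, TMM-scaled CPM), 1 point per library, coloured by group. The 10 female libraries lie at or below 5.34 CPM of Y-linked RNA, and HFD.male 2 lies between the groups on the Xist axis at 353.5 CPM.

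In male cones, the question was which genes differed between obese and control dams. Bdh1, which encodes the mitochondrial 3-hydroxybutyrate dehydrogenase of ketone body metabolism (mm10 chromosome 16, 31422280 to 31458901, plus strand), was the 1 gene of 18795 that passed the test. It fell from 24.6 ± 1.87 CPM (SD, n = 4) in control males to 8.92 ± 2.27 CPM (SD, n = 4) in obese males, a log2 fold change of -1.46 (SE 0.22, adjusted p = 0.0287), with every obese male below every control male. Of the next genes by p-value, none passed. Cldn4, the tight-junction protein claudin 4 (chromosome 5, 134945119 to 134946934, minus strand), stood at 29.1 ± 2.60 CPM in control and 56.7 ± 5.07 CPM in obese males (log2 fold change 0.97, SE 0.17, adjusted p = 0.0926), and St14, the membrane protease matriptase, at 38.6 ± 4.42 and 72.2 ± 10.8 CPM (0.91, SE 0.16, adjusted p = 0.0926). Glul, which encodes glutamine synthetase, had a log2 fold change of 0.58 (SE 0.12). For the transcription factor gene Runx1, at 15.9 ± 2.57 CPM in control and 42.9 ± 26.7 CPM in obese males, the value was 1.43 (SE 0.29), and 0.91 without HFD.male 2. For Serpine1, which encodes plasminogen activator inhibitor 1, it was 2.24 (SE 0.48), and 1.35 with the decidual level as a covariate. For Dhrs3, a retinaldehyde reductase gene, the value was 1.87 (SE 0.41), for the scavenger receptor gene Colec12 1.62 (SE 0.35), for the X-linked zinc finger gene Zfp449 1.10 (SE 0.23) and for the transcription factor gene Rfx7 -0.45 (SE 0.09). These last 7 genes had an adjusted p of 0.249.

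As a group, ribosomal protein genes shifted down in obese males: 34 of the 35 measured had a negative log2 fold change, with a median of -0.23 (camera adjusted p = 2.53e-06), including Rpl35 at -0.58 and Rpl22 at -0.35. Nuclear-encoded genes of oxidative phosphorylation shifted down as well, with 25 of 30 negative and a median of -0.18 (adjusted p = 0.00273), such as Cox7a2 at -0.53 and Cycs at -0.48. Hypoxia and glycolysis genes shifted up, with 29 of 34 positive and a median of 0.30 (adjusted p = 2.91e-05). Its leading members were Pfkfb4 at 2.28, a regulator of glycolytic flux, Epas1 at 1.44, which encodes the hypoxia-inducible factor HIF-2 alpha, and Ndrg1 at 0.60, a hypoxia-induced gene. Cholesterol synthesis genes were positive in 24 of 25 cases (median 0.36, adjusted p = 0.00134), led by Srebf2 at 0.61, the transcription factor of sterol synthesis. Lipid synthesis genes were positive in 14 of 19 cases (median 0.24, adjusted p = 0.0304), although Elovl5, a fatty acid elongase gene, stood at -0.37. Markers of extraembryonic endoderm were positive in 22 of 25 cases (median 0.53, adjusted p = 0.00134), led by the endoderm transcription factor genes Sox17 at 0.83 and Sox7 at 0.86. Extracellular matrix and invasion genes (18 of 22 positive, median 0.40, adjusted p = 0.00134) and apoptosis and p53 target genes (16 of 20 positive, median 0.54, adjusted p = 0.00386) also shifted up. Markers of the maternal decidua, the uterine tissue around the cone, were positive in 16 of 21 cases with a median of 1.5 (adjusted p = 0.00134), including Cryab at 2.46 and Hand2 at 3.06. Each of these 9 list calls used a preset correlation between genes, and each was lost with an estimated correlation (adjusted p = 0.763 for each). No member of the lists passed the test over all genes; adjusted over the list alone, 5 decidual genes and 2 matrix genes did.

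Without HFD.male 2 the decidual median was 0.84 (adjusted p = 0.0940), the matrix median 0.12 (adjusted p = 0.340) and the apoptosis median 0.08 (adjusted p = 0.484). With the decidual level as a covariate the matrix median was 0.22 (adjusted p = 0.149) and the apoptosis median 0.26 (adjusted p = 0.0955). Other list calls ended without Control.male 1 (apoptosis, 0.0508), Control.male 2 (oxidative phosphorylation, median -0.12, 0.0730) or HFD.male 3 (endoderm, median 0.31, 0.0566), and lipid synthesis ended without Control.male 2 (0.108), HFD.male 1 (0.229), HFD.male 3 (0.0900) or HFD.male 4 (0.0521), each value an adjusted p. Some medians moved with the call kept: cholesterol synthesis was 0.18 without HFD.male 1, endoderm 0.34 without Control.male 1 and matrix 0.63 without Control.male 4. With GC and length trends removed, the oxidative phosphorylation median was -0.05 (adjusted p = 0.375) and the lipid synthesis median 0.15 (adjusted p = 0.170), while the ribosomal median was -0.11 and the endoderm median 0.35, both with the call kept. The Bdh1 call ended without any of the male libraries other than HFD.male 3 (adjusted p from 0.0679 to 0.155, log2 fold change from -1.51 to -1.39), with scaling by library size alone (adjusted p = 0.0545) and in a fit of the 8 male libraries alone (adjusted p = 0.134). Without HFD.male 3 there were 16 called genes, and DESeq2 called 90 genes, 52 higher and 38 lower.

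In female cones, no gene passed the edgeR test between obese and control dams. The smallest adjusted p was 0.625, and 1452 genes had an unadjusted p below 0.05 against 939.8 expected by chance, a count of 953 without Control.female 5 (934.9 expected) and up to 1762 without another library. It was 2463 with GC and length trends removed (909.2 expected) and 3332 with no filter on low counts (1632.8 expected). DESeq2 called 2 genes and limma 0, and a fit of the 10 female libraries alone called 66, all higher. Among the genes with the smallest p-values, Vstm5 stood at 6.34 ± 1.24 CPM (SD, n = 5) in control and 12.7 ± 2.02 CPM (SD, n = 5) in obese females, a log2 fold change of 1.00 (SE 0.20). Ndrg1 had a value of 0.74 (SE 0.19), and Mgarp, which encodes a mitochondrial protein, 1.03 (SE 0.24). Nt5c2, a cytosolic nucleotidase gene, had a value of 0.48 (SE 0.12), and 0.31 with GC and length trends removed. Rps8 stood at -0.44 (SE 0.11), the ribosomal protein pseudogene Rpl36a-ps3 at -0.88 (SE 0.21) and Eif3h, a subunit of translation initiation factor 3, at -0.35 (SE 0.09). Haus2, a gene of the spindle augmin complex, stood at -0.75 (SE 0.17) and Smim1 at -1.21 (SE 0.27). The value of 3.63 for Lect1 (SE 0.91) followed 1 library, HFD.female 3, at 18.6 CPM against at most 3.31 CPM in the other obese females, and was 1.80 on the normalized table.

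In female cones 6 gene lists passed the camera test. A sign of RNA quality moved with them: Malat1 stood at 994 to 2086 CPM in control and 2458 to 5628 CPM in obese females, and the list of nuclear noncoding RNAs had a median of 0.30 (adjusted p = 0.0981). Oxidative phosphorylation genes shifted down, with 28 of 30 negative and a median of -0.21 (camera adjusted p = 2.39e-06), led by Cox7b at -0.40 and Ndufa4 at -0.52. Ribosomal protein genes shifted down with 28 of 35 negative (median -0.17, adjusted p = 0.00307), and hypoxia and glycolysis genes shifted up with 31 of 34 positive (median 0.19, adjusted p = 6.80e-04). Within the last list Hif1a itself, which encodes hypoxia-inducible factor 1 alpha, stood at -0.33. Decidual markers shifted up, with 13 of 21 positive and a median of 0.32 (adjusted p = 0.0110), led by Angpt2 at 1.75 and Htra1 at 1.52. Genes of the unfolded protein and integrated stress responses shifted down with 16 of 24 negative (median -0.14, adjusted p = 0.0110), including the endoplasmic reticulum chaperone genes Calr at -0.29 and Pdia3 at -0.25. Cell cycle genes shifted down with 24 of 29 negative (median -0.11, adjusted p = 0.0130), such as Rrm1 at -0.26 and Cdk1 at -0.26. All 6 calls were lost with an estimated correlation (adjusted p = 0.815 for each). Over all genes no member passed, and adjusted over the list alone 1 oxidative phosphorylation and 2 stress response genes were lower and 1 hypoxia gene was higher. HFD.female 3 was the shallowest library, and without it the cell cycle median was -0.07 (adjusted p = 0.419), a call that also ended without HFD.female 1 (adjusted p = 0.0568), with library size alone (median -0.08, adjusted p = 0.0556) and with the decidual covariate (median -0.04, adjusted p = 0.355). The hypoxia median was 0.36 without Control.female 1 and 0.07 with GC and length trends removed, and the ribosomal median was -0.11 with the decidual covariate, each with the call kept. The decidual median was 0.02 without Control.female 2 (adjusted p = 0.173), 0.07 without Control.female 1 (adjusted p = 0.0766), 0.29 without HFD.female 1 (adjusted p = 0.0887) and 0.08 with no filter on low counts (adjusted p = 0.184). With the call kept it was 0.10 without Control.female 3, 1.37 without Control.female 4, 0.61 without Control.female 5, 0.56 without HFD.female 4, 0.52 without HFD.female 5, and 0.79 and 0.63 with limma-trend before and after GC and length removal. The stress response call ended without HFD.female 2 (adjusted p = 0.0704), and the ribosomal call with GC and length trends removed, where its median stayed at -0.16 (adjusted p = 0.0836). That removal left the stress response median at -0.26 and the cell cycle median at -0.21, with both calls kept.

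Averaged over both sexes, the comparison of obese with control dams used all 18 libraries. Again no gene passed the edgeR test, with Bdh1 closest (log2 fold change -0.93, SE 0.14, adjusted p = 0.05004). At an unadjusted p below 0.05 there were 2844 genes, 1485 higher and 1359 lower, against 939.8 expected by chance (1721 with the decidual covariate), and 246 genes had an adjusted p below 0.1, 143 higher and 103 lower. Cldn4 had a log2 fold change of 0.68 (SE 0.11) and Colec12 of 1.38 (SE 0.24), both with an adjusted p of 0.0649. The remaining genes named by the fixed rule had an adjusted p of 0.0740. Those with positive values were Glul at 0.42 (SE 0.08), the semaphorin gene Sema3g at 3.44 (SE 0.64) and Parm1 at 1.51 (SE 0.29). Those with negative values were the endocytic trafficking gene Ehd4 at -0.43 (SE 0.08), the beta-tropomyosin gene Tpm2 at -0.66 (SE 0.12), the tyrosine phosphatase gene Ptpn12 at -0.54 (SE 0.10) and the kinase gene Stk10 at -0.57 (SE 0.11). Sema3g varied widely between obese embryos, at 32.6 ± 40.3 CPM (SD, n = 4) in males and 16.9 ± 7.54 CPM (SD, n = 5) in females, against 2.04 ± 2.12 and 2.23 ± 1.56 CPM in controls. With the decidual covariate Sema3g stood at 2.13 and Parm1 at 0.79.

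**Figure D2:**
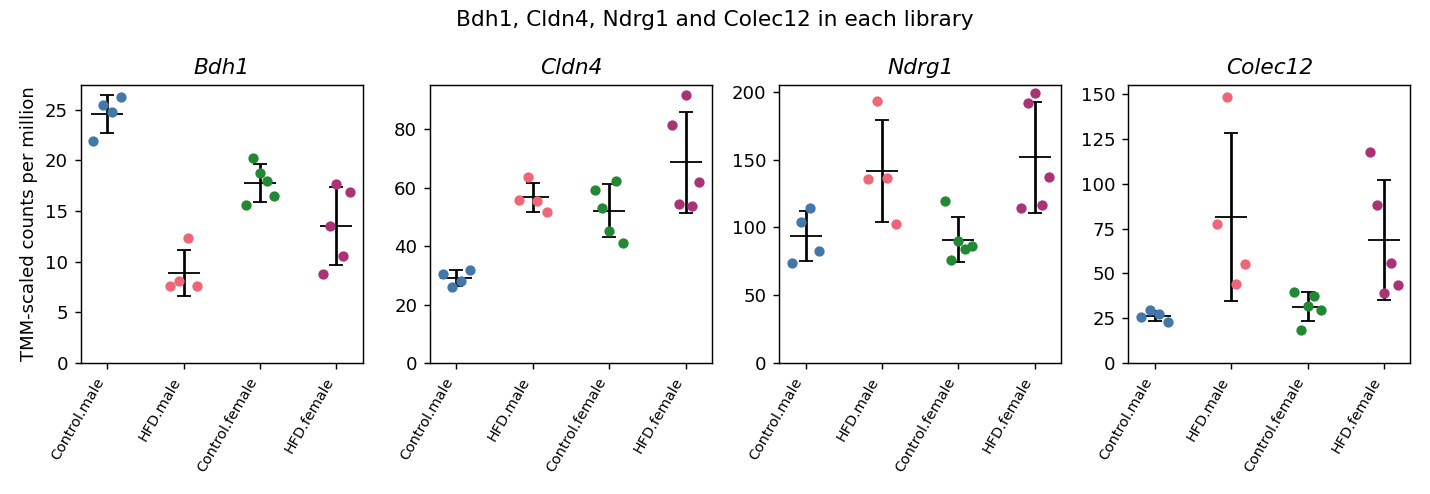
Level of Bdh1, Cldn4, Ndrg1 and Colec12 (vertical axes, TMM-scaled CPM) in each library, with points for embryos, bars for group means and whiskers for ± 1 SD (n = 4 males and 5 females per diet). Bdh1 averages 24.6 CPM in control males and 8.92 CPM in obese males, with 17.8 and 13.5 CPM in females.

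In this average, 33 of the 34 hypoxia and glycolysis genes had positive values (median 0.20, camera adjusted p = 1.04e-06). Ndrg1 stood at 0.67, Pfkfb4 at 1.76 and Mxi1, a MYC antagonist gene, at 1.48, while Hif1a was the negative member at -0.29. Adjusted over the list alone, 8 members were higher and 1 was lower. Ribosomal protein genes were negative in 32 of 35 cases (median -0.19, adjusted p = 9.13e-07), for example Rpl4 at -0.23 and Rpl32 at -0.20, and oxidative phosphorylation genes in 28 of 30 (median -0.16, adjusted p = 1.28e-06), with Cox7b at -0.30 and Cox6b1 at -0.39. Cell cycle genes shifted down (22 of 29 negative, median -0.11, adjusted p = 0.00727), with Ccna2 at -0.21. Decidual markers shifted up (15 of 21 positive, median 0.96, adjusted p = 2.32e-04), with Angpt2 at 1.71 and Htra1 at 1.55. Cholesterol synthesis (23 of 25 positive, median 0.20, adjusted p = 0.00878), apoptosis and p53 targets (14 of 20, median 0.46, adjusted p = 0.0132), interferon response (22 of 25, median 0.49, adjusted p = 0.0223) and extracellular matrix genes (16 of 22, median 0.19, adjusted p = 0.0410) shifted up. With an estimated correlation all 9 calls were lost: the adjusted p was 0.638 for the ribosomal, hypoxia, oxidative phosphorylation, decidual, apoptosis and interferon lists. It was 0.718 for cell cycle, 0.732 for matrix and 0.752 for cholesterol synthesis.

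Adjusted over the list alone, 7 decidual, 2 interferon and 6 matrix genes were higher, and 7 oxidative phosphorylation genes and 1 matrix gene were lower, with no member past the test over all genes. Malat1, from the list fixed as a sign of RNA quality, had a log2 fold change of 1.29 (SE 0.34), and that list as a whole did not pass (adjusted p = 0.231).

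Without HFD.male 2 the apoptosis median was 0.16 (adjusted p = 0.140), the interferon median 0.24 (adjusted p = 0.317) and the matrix median 0.10 (adjusted p = 0.434). With the decidual covariate these were 0.16 (adjusted p = 0.251), 0.12 and 0.13 (adjusted p = 0.735 for both), and the cell cycle median was -0.04 (adjusted p = 0.305). The matrix call also ended without Control.male 1, Control.female 2, 3 or 5, or HFD.female 1, 3 or 5 (adjusted p from 0.0526 to 0.109), with GC and length trends removed (median 0.07, 0.438) and with no filter on low counts (median 0.12, 0.0826). Without both libraries that stand apart the apoptosis (0.14), interferon (0.16), matrix (0.07) and cell cycle (-0.03) calls ended. The interferon call ended without Control.male 1 or 3, Control.female 1 or HFD.female 1 (adjusted p from 0.0545 to 0.104), apoptosis without Control.male 1 (0.0601), cell cycle without HFD.female 3 (median -0.08, 0.0628) and cholesterol without HFD.male 1 (median 0.15, 0.0551) or HFD.female 2 (median 0.10, 0.0951). With the call kept, the cholesterol median was 0.39 without Control.female 1 and 0.11 without HFD.female 3, the hypoxia median 0.32 without Control.female 1 and the decidual median 0.57 without HFD.male 2, 0.46 without both libraries and 0.56 with no filter. The cholesterol median was 0.32 with the decidual covariate and the apoptosis median 0.28 with GC and length trends removed. With single libraries left out, edgeR called 325 genes without HFD.male 3, 98 without Control.male 2, 73 without HFD.male 4, 56 without Control.female 1, 26 without HFD.female 5, 12 without HFD.male 2 and 4 without HFD.female 3, and 0 without any other. DESeq2 called 597 genes, limma voom 89 and limma-trend on normalized values 1, while 317 were called with no filter on low counts and 21 with scaling by library size alone.

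**Figure D3:**
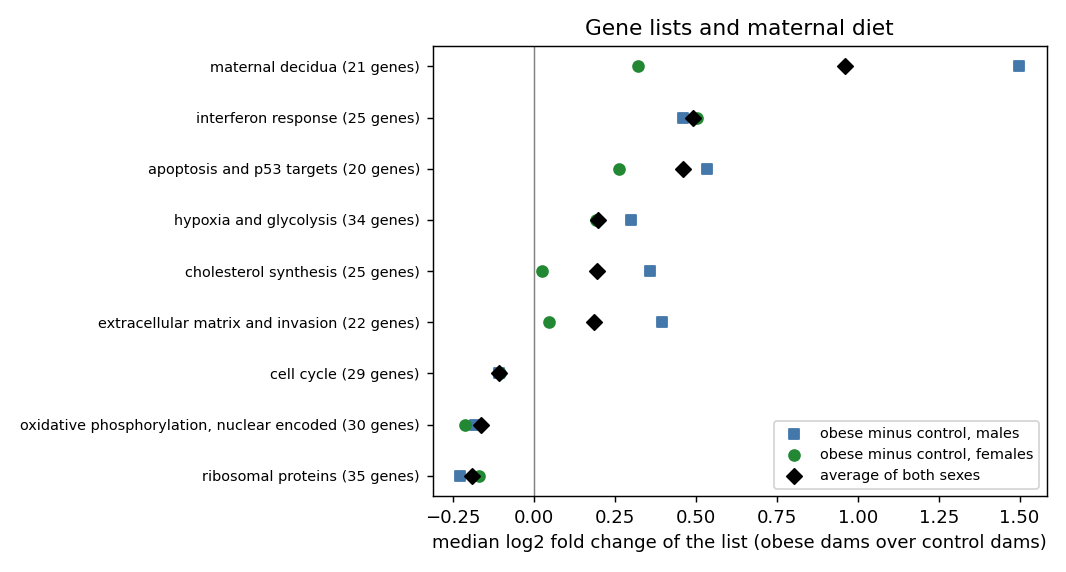
Median log2 fold change of obese over control dams (horizontal axis) for the 9 gene lists past a camera adjusted p of 0.05 in the average of both sexes, with squares for males, circles for females and diamonds for the average. Decidual markers lie at 1.5 in males and 0.32 in females, and the ribosomal and oxidative phosphorylation lists lie below 0 in both.

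Male and female embryos share no libraries, so their diet effects could be set against each other. They may still share litters or batches, which the labels do not give, so the effects need not be independent. Across the 18795 genes, which are not independent replicates, the log2 fold changes had a Pearson correlation of 0.236 and a Spearman correlation of 0.27, and 63% of genes had the same sign. Without HFD.male 2 the Pearson correlation was 0.075, and with the decidual level as a covariate it was 0.103.

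Whether the diet effect differed between the sexes was tested as an interaction, the female effect minus the male effect. No gene passed in edgeR, DESeq2 or limma. In edgeR 597 genes had an unadjusted p below 0.05 against 939.8 expected, but the count was 971 without HFD.male 2 (983.9 expected), 1033 with limma voom (939.8 expected), 922 with DESeq2 (1626.5 expected) and 1727 with no filter on low counts (1632.8 expected). Bdh1, past the threshold in males but not in females, had an interaction of 1.06 (SE 0.29, adjusted p = 1). The values were -1.28 for Zfp449 (SE 0.31), -0.87 for St14 (SE 0.21), -0.74 for the potassium channel subunit gene Kcng1 (SE 0.19) and -0.64 for the nuclear receptor coactivator gene Ncoa2 (SE 0.19). They were 1.18 for the cytochrome oxidase assembly gene Cox18 (SE 0.33), 0.41 for Rfx7 (SE 0.12), -1.05 for Cdc34b (SE 0.30), 3.93 for Tmprss9 (SE 1.11) and -3.91 for Trim15 (SE 1.14), the last 2 at about 1 CPM and at 0.92 and -1.92 on the normalized table. Extraembryonic endoderm markers had a lower diet effect in females than in males, negative in 23 of 25 cases with a median of -0.60 (camera adjusted p = 2.05e-04). Sox7 stood at -1.11 and Gata4 at -0.71. Extracellular matrix genes (20 of 22 negative, median -0.37, adjusted p = 0.0209) and stress response genes (18 of 24 negative, median -0.23, adjusted p = 0.0258) did so too. With an estimated correlation the 3 calls were lost (adjusted p = 0.911 for each), and without HFD.male 2 the matrix median was -0.10 (adjusted p = 0.453) and the stress response median -0.10 (adjusted p = 0.370). Both calls also ended without Control.male 1 (0.0744 and 0.286), Control.female 1 (0.0649 and 0.0592) or HFD.female 2 (0.0547 and 0.104), and the matrix call without HFD.female 4 (0.0954). The stress response call ended with library size alone (median -0.17, 0.0776) and with no filter on low counts (median -0.22, 0.0554). The endoderm median was -0.36 without Control.female 1 and the matrix median -0.63 without HFD.male 3, both with the call kept.

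Between the sexes, embryos of control dams differed in 8 genes, 4 higher and 4 lower in females. As embryos were sexed from RNA, calls of Xist, the Y-linked genes and their list were largely fixed in advance in both diets. Xist was higher in females by a log2 fold change of 4.76 (SE 0.65, adjusted p = 0.00142), at 1140 ± 183 CPM (SD, n = 5) against 42.0 ± 19.6 CPM (SD, n = 4). The X-linked ribosomal protein gene Rps4x (0.64, SE 0.11, adjusted p = 0.0203) and Taf1, the X-linked subunit of general transcription factor TFIID (0.59, SE 0.09, adjusted p = 0.00807), were also higher. The fourth was the processed pseudogene Gm9294 on chromosome 7 (0.94, SE 0.12, adjusted p = 7.36e-04), which falls outside the rule for named genes and was chosen after its values were seen. The 4 lower genes were the Y-linked Ddx3y, Eif2s3y, Kdm5d and Uty. Ddx3y had 78.1 ± 6.05 CPM in males and no counts in females, at least 3297-fold higher in males against a floor of 3 counts over the group, and Eif2s3y was at least 1366-fold higher. The floor covers counting error only. Kdm5d stood at 26.3 ± 3.43 CPM in males with 2 counts in females, and Uty at 31.8 ± 3.70 CPM against 0.145 CPM. The 3 genes named by their small p did not pass: Cldn4 (0.84, SE 0.16, adjusted p = 0.0915), Rpl37rt (-1.06, SE 0.21, adjusted p = 0.0970) and the small nuclear RNA gene Scarna13 (-1.65, SE 0.35, adjusted p = 0.221). Tsix, the antisense partner of Xist, stood at -0.30 (SE 0.48) and the low-level Uba1y at -3.74 (SE 1.76), both with an adjusted p of 1. The Rps4x call ended without any of the libraries other than Control.female 2 (adjusted p from 0.0740 to 0.202), with library size alone (0.0502) and in a fit of the 2 groups (0.0530). Taf1 ended without Control.male 2 (0.0682) or Control.male 4 (0.0543) and in that fit (0.113). The other 6 calls were kept in each of these fits.

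X genes known to escape inactivation shifted up in control females, with 10 of 13 positive and a median of 0.38 (camera adjusted p = 0.00112, 0.0663 with an estimated correlation), as did the X-inactivation RNAs (3 of 4 positive, adjusted p = 5.84e-04, 0.0547 with an estimated correlation). The X-inactivation list holds Xist, so in both diets its call was in part fixed in advance by sexing from RNA. It also shares Jpx and Ftx with the escape list, so the calls of these lists are not independent. The X chromosome as a whole gave 3.24 ± 0.1001 counts per 100 autosomal counts in control females and 3.13 ± 0.0689 in control males, leaving out Xist (exact permutation test, two-sided, p = 0.103). Extraembryonic endoderm markers were positive in all 25 measured cases (median 0.37, adjusted p = 1.58e-06), lipid synthesis genes in 18 of 19 (median 0.34, adjusted p = 1.18e-04), cholesterol synthesis genes in 23 of 25 (median 0.35, adjusted p = 0.00347) and oxidative stress genes in 17 of 24 (median 0.15, adjusted p = 0.0234). Nuclear and structural noncoding RNAs, a list fixed as a sign of RNA quality, were lower in all 7 cases (median -0.42, adjusted p = 0.00137). With an estimated correlation these calls were lost (adjusted p = 0.359 for endoderm, lipid synthesis and oxidative stress, 0.806 for cholesterol and 0.0547 for the noncoding RNAs). Without Control.female 1 the cholesterol median was 0 (adjusted p = 0.985), the lipid synthesis median 0.17 (adjusted p = 0.0472) and the endoderm median 0.22, and without Control.male 4 the endoderm median was 0.56 and the escape gene median 0.25. The noncoding RNA median was -0.27 without Control.male 2. The oxidative stress call ended without Control.male 3 (0.111), Control.male 4 (0.0844) or Control.female 4 (0.0509) and with no filter on low counts (0.0602). With GC and length trends removed the lipid synthesis median was 0.12 and the escape gene median 0.23, both with the call kept. DESeq2 called 21 genes. The Y-linked list kept its call with an estimated correlation (adjusted p = 3.82e-07).

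Embryos of obese dams differed between the sexes in 10 genes, 6 higher and 4 lower in females, and 7 of these were also called in control embryos in the same direction (Xist, Rps4x, Gm9294 and the 4 Y-linked genes). Xist was higher by a log2 fold change of 3.49 (SE 0.61, adjusted p = 0.0282), at 1330 ± 322 CPM (SD, n = 5) against 118.8 ± 158 CPM (SD, n = 4), the male value including HFD.male 2. Rps4x (0.75, SE 0.11, adjusted p = 0.00436) and Ogt, the X-linked O-GlcNAc transferase gene (0.62, SE 0.11, adjusted p = 0.0282), were higher as well. The other 3 were the pseudogenes Gm9294 (0.79, SE 0.12), Gm13680 on chromosome 2 (0.79, SE 0.13) and Gm2223 on chromosome X (0.58, SE 0.10). Ddx3y was at least 1667-fold higher in males, at 60.5 ± 10.7 CPM. Kdm5d, Eif2s3y and Uty averaged 23.8 ± 7.17, 20.4 ± 10.5 and 33.0 ± 4.99 CPM in males and 0.0368, 0.192 and 0.368 CPM in females. Tsix stood at 0.31 (SE 0.48), and Uba1y at 0.37 (SE 1.54), its level in females coming from HFD.female 3. Escape genes (11 of 13 positive, median 0.32, camera adjusted p = 0.00248) and X-inactivation RNAs (4 of 4 positive, adjusted p = 0.00168) shifted up, both with an adjusted p of 0.112 with an estimated correlation, and the escape gene median was 0.14 with GC and length trends removed. Stress response genes shifted down, with 19 of 24 negative and a median of -0.21 (adjusted p = 0.00168, 0.738 with an estimated correlation), among them Calr at -0.40, Pdia6 at -0.34 and Hsp90b1 at -0.30. Without HFD.male 2 that median was -0.06 (adjusted p = 0.224). The X chromosome gave 3.13 ± 0.143 counts per 100 autosomal counts in obese females and 3.03 ± 0.255 in obese males (exact permutation test, two-sided, p = 0.524), where HFD.male 2 had 2.66 and the males without it averaged 3.15, above the females. The count of called genes was 5 without HFD.male 1, 5 without HFD.male 3 and 6 without HFD.male 4. The Xist call was kept without HFD.male 2 (5.04) or HFD.female 2 and ended without any other library (3.15 to 3.57, adjusted p from 0.0508 to 0.196) and with a robust fit (0.265). Ogt ended without HFD.male 1, 2, 3 or 4 or HFD.female 2 or 4 (0.0575 to 0.159), without both libraries that stand apart (0.0810) and with GC and length trends removed (0.0654). Of the 9 libraries, Gm13680 and Gm2223 each kept their call without 2, Gm9294 without 7, and Rps4x and the Y-linked genes without all 9. DESeq2 called 35, and a fit of these 9 libraries alone called 4, without Xist (0.754), Ogt (0.619), Gm2223 (0.387), Gm9294 (0.226), Rps4x (0.0984) or Eif2s3y (0.0909), the last also lost with limma voom (0.0618).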

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

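The gap test for single libraries was fixed before the data were examined, and the tests of explanations for HFD.male 2 were chosen after its values were seen. A library was listed where its gap to the nearest other library exceeded Dixon's 95% critical value, which chance does in about 1 in 20 groups. Of 244 groups tested 21 exceeded it, against 12.2 expected by chance.

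HFD.male 2 stood apart in several measures: Xist at 353.5 CPM against 22.3 to 75.2 CPM in the other obese males, the endoderm list at a mean log2 CPM of 5.96 against 6.96 to 7.12, and the apoptosis list at 5.40 against 4.10 to 4.26. The trophoblast progenitor list, looked at after its values were seen, was at 3.36 in HFD.male 2 against 6.12 to 6.34 in the other obese males. Every other library had at least 5.55. Its decidual list, at 4.74 against 4.59 in Control.female 4 and 4.06 in HFD.male 1, did not stand apart by the gap test. Of the 21 decidual markers, 10 exceeded every other library, among them Prl8a2 at 1307 CPM and Htra1 at 869.2 CPM. Postn and Dcn were at 0 CPM, but reached at most 1.78 and 2.15 CPM in any other library. Hoxa11, Col1a2, Esr1 and Col3a1, which also did not exceed all others, had low medians of 0.668 to 2.24 CPM in the other libraries. Wnt6 went the other way, at 1.45 CPM against a median of 10.06 CPM in the other libraries. Des, Col1a1, Bmp2 and Wnt4 lay above the median of the other libraries but below the highest of them. Of the list's genes, 4 (Hand2, Bmp2, Cdh5 and Angpt2) also stand in other lists. A female embryo with a wrong label is argued against by Y-linked RNA 19.1 times that of the highest female library. Malat1 at 2.67 times the highest of the others argues against a library made only of other libraries' reads, but cannot decide on a part. Apob at 145.5 CPM, against at least 1640 CPM in every other library, limits the size of such a part. For the Xist and decidual levels, maternal tissue in the library is a candidate explanation that cannot be told apart here from a difference in the cone itself. The Y-linked sum of HFD.male 2 was 0.708 of the lowest other male library and 36.51% below the mean of the other males. Its Xist reached 26.15% of the female mean once the mean of the other males was taken off both. Both values go with maternal tissue but rest on 1 library, and 11 of the 21 markers did not exceed all others. The fall in Apob, to 145.5 CPM against at least 1640 CPM, was far larger than 36.51%. Dilution on the scale of the Y-linked sum would thus not by itself give the Apob level of this library. Over the 8 male libraries log2 Xist and the decidual level had a Pearson r of 0.755 (exact permutation p = 0.0277, 0.0555 adjusted over 2 relations) and a Spearman rho of 0.762 (exact permutation p = 0.0368, 0.0735 adjusted). Without HFD.male 1 and HFD.male 2 r was 0.223 (exact permutation p = 0.642) and rho 0.429 (exact permutation p = 0.419), so the relation rests on those libraries. They were left out as farthest from the median Xist level, so this drop cannot decide on maternal tissue. The second relation, log2 Xist with the Y-linked sum, had an r of -0.772 (exact permutation p = 0.114, also adjusted) and a rho of -0.238 (exact permutation p = 0.582, also adjusted), and an r of 0.363 without those libraries (exact permutation p = 0.347).

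Other single libraries lay apart from their group. Control.female 3 had 54.26 M counts against 16.69 to 19.38 M. Gm26917 took 8.48% of counts in Control.male 2 against 12.24% to 12.48%, and Xist there was 71.1 CPM against at most 36.5 CPM. The Y-linked sum was 187.4 CPM in Control.male 1 against at most 163.2 CPM. Bdh1 was 12.3 CPM in HFD.male 3 against at most 8.12 CPM in the other obese males. Runx1 was 35.8 CPM in HFD.female 1 against at most 27.5 CPM, and Dhrs3 was 5.65 CPM in Control.female 4 against at most 4.21 CPM. Smim1 was 7.52 CPM in Control.male 4 against at most 4.603 CPM. In HFD.male 4, Rps8 was 66.0 CPM against at least 77.8 CPM, and Rpl36a-ps3 was 34.5 CPM against at most 19.9 CPM. In HFD.female 3, Lect1 was 18.6 CPM against at most 3.31 CPM, Tmprss9 was 3.95 CPM against at most 1.56 CPM, and the cell cycle list was at 6.79 against at least 7.03. Rps4x was 142.6 CPM in Control.male 3 against at least 160.8 CPM, and 191.5 CPM in Control.female 2 against at least 251.7 CPM. Uba1y was 1.49 CPM in Control.male 3 against at most 0.247 CPM. In Control.female 1 the lipid synthesis list was at 6.17 against at most 5.44 and the cholesterol list at 5.74 against at most 4.70.

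For 3 lists the diet effect differed between the sexes in the interaction test with the preset correlation: extraembryonic endoderm with a median of -0.60, extracellular matrix with -0.37 and the stress responses with -0.23. With an estimated correlation none of the 3 passed (adjusted p = 0.911 for each).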

How the results depend on the processing

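Fits without HFD.male 2 and HFD.female 3, with a decidual covariate and with GC and length trends removed were chosen after seeing the data; the others were fixed before. The cause of each change below was not tested. For diet in males (1 gene), the count was 0 with library size alone, in a fit of the 2 groups alone, without both libraries that stand apart and with the decidual covariate, 9 with no filter, 3 with a robust fit, 3 at an adjusted p of 0.1, 3 with limma voom and 90 with DESeq2; leaving out single libraries gave 0 to 16. For diet in females (0), DESeq2 gave 2 and a fit of the 2 groups 66; leaving out libraries gave 0 to 0. For the average (0), the count was 21 with library size alone, 317 with no filter, 9 with a robust fit, 246 at an adjusted p of 0.1, 597 with DESeq2, 89 with limma voom, 1 on the normalized table, 3 without both libraries, 1 with limma-trend and 38 once GC and length trends were removed; leaving out libraries gave 0 to 325. The interaction stayed at 0 in every setting, 0 to 0 without single libraries. Sex in controls (8) gave 21 with DESeq2, and 6 to 10 without single libraries. Sex in obese embryos (10) gave 35 with DESeq2, 4 in a fit of the 2 groups, and 5 to 11 without single libraries. The correlation of the male and female diet effects (0.236) was 0.378 with the CPM filter, 0.362 over genes with an unadjusted p below 0.05, 0.076 without both libraries, 0.103 with the decidual covariate, and 0.075 to 0.275 without single libraries.

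With the replicate number as a block, the average called 1 gene (Bdh1), the averaged matrix list lost its call (0.17, adjusted p = 0.0606), the decidual list in females was 0.75, the correlation of diet effects was 0.179, and the value of Uba1y, sex in obese embryos, was -2.295. The numbers did not pair the libraries: 25 same-numbered pairs had correlations from -0.18 to 0.252, 2 of them above 0.1, and 6 of 18 libraries correlated best with their own number.

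Signs reversed for Uba1y, sex in obese embryos (0.37), which ranged from -3.78 to 0.71 without single libraries and was -2.99 with limma voom, -0.23 on the normalized table, -3.78 without HFD.female 3, -3.49 without both libraries, and -1.48 and -1.59 with limma-trend before and after GC and length removal. Tsix, sex in controls (-0.30), was 0.0030 without Control.male 1 and ranged from -0.66 to that value without single libraries. With its own level as covariate the decidual list was -0.14 in females, and its median also turned negative in males (-0.24) and in the average (-0.30). The cholesterol list in controls was 0 without Control.female 1, with a range of 0 to 0.46 without single libraries. Another 1712 values covered the named genes together with the counts of genes with an unadjusted p below 0.05. Of these, 1491 stayed the same, meaning direction and call for genes and a similar size for counts. Named genes gained the call in 154 values, lost it in 45 and reversed sign in 8, and 14 counts moved. Of 885 list values, 768 kept direction and call and 115 lost the call. In simulated data only 10% of 1.5-fold and 40% of 2-fold changes were recovered in males, so changes of that size could often be missed at this depth and n.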

Other observations

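The tests for GC content and length, for the libraries that stand apart, for maternal tissue and for other splits were chosen after the results were seen. For the split of the 3 lists and the search for shared sequence, the possible outcomes were written down before the test was run. The lists and pseudogenes used there had still been picked from their results. Several trophoblast genes had large values in the diet average without a shift of their list. Among giant cell markers, Prl3d1, which encodes placental lactogen 1, stood at -1.001 (SE 0.33) and Prl7a1 at -1.50 (SE 0.41), while Prl6a1 stood at 2.14 (SE 0.72) and Lifr at 1.088 (SE 0.35). Adjusted over the list alone 6 of these markers were higher and 4 lower, and the list's median was -0.04, its mean 0.17 and its camera direction up (adjusted p = 0.895). In the cone and spongiotrophoblast list 5 were higher and 1 lower over the list alone, with Psg19 at 2.17 (SE 0.59) and Plet1 at -0.54 (SE 0.15). Dlx3, a transcription factor of labyrinth development, stood at -0.79 (SE 0.19), the progenitor factor Gata3 at -0.50 (SE 0.15) and the imprinted Cdkn1c at -0.47 (SE 0.17). The macrophage receptor gene Csf1r stood at 2.38 (SE 0.63) and the cholesterol exporter gene Abca1 at 2.54 (SE 0.66). Their lists, of leukocytes and of fatty acid uptake, did not pass in the diet average. None of these genes passed the test over all genes.

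In the diet average the ribosomal and oxidative phosphorylation lists were lower and the hypoxia and glycolysis list higher. GC content and length trends are argued against as the whole cause, since each median kept at least 0.64 of its size after their removal. The same holds for the 2 libraries that stand apart (at least 0.759). With the decidual covariate each median kept at least 0.723 of its size. That score was not shown to measure maternal tissue, so the covariate cannot decide on maternal tissue as a cause. Every list was still past the preset test in these 3 fits. Within 1 sex the GC and length removal weighed more, with the oxidative phosphorylation median at -0.05 in males and the hypoxia median at 0.07 in females, and RNA quality was not tested as a cause. The mean size of the 3 medians, 0.184, exceeded the highest other split, 0.177 (1 of 100 splits, the real one included), but the 3 lists were picked from 38 after their results were seen. All 3 calls were lost with an estimated correlation (adjusted p = 0.638 for each), and litter, dam or batch may differ between the diets, which the labels do not resolve.

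Of the pseudogenes higher in females, Gm2223 on chromosome X shared 100% of its 50-base stretches with transcripts of the X-linked Eif2s3x, which is consistent with shared reads. Gm9294 on chromosome 7 shared 25% and Gm13680 on chromosome 2 shared 32.3%, both with the X-linked Rps4x, so their source cannot be told apart here.

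Other splits of the same libraries into groups of the same sizes gave as large a result as follows, the real split included. For diet in males, 3 of 35 splits called as many genes (real 1, highest other 230), 1 gave as many genes at an unadjusted p below 0.05 (1852, 1628) and 14 as many lists (9, 17). For diet in females these were 100 of 100 (0, 1), 4 (1452, 1587) and 29 (6, 14). For the diet average they were 100 of 100 (0, 129), 1 (2844, 2805) and 31 (9, 16). For the interaction they were 100 of 100 (0, 1), 76 (597, 1905) and 89 (3, 17). For sex in controls they were 1 of 100 (8, 7), 2 (896, 1124) and 42 (8, 13), and for sex in obese embryos 3 (10, 95), 34 (1232, 2843) and 64 (4, 18). The correlation of the diet effects was reached by 1 of 100 (0.236, 0.223). These splits treat embryos as exchangeable, although litters, which are not given, would lie within a diet. For the correlation, males and females were split separately, which breaks up any litter or batch that they share. On that footing chance was excluded at 5% for the unadjusted counts of the 3 diet comparisons and for the correlation. It was also excluded for the genes called between the sexes, but Xist and the Y-linked genes among them follow from sexing by RNA. For sex in controls 2 of 100 splits reached the unadjusted count of 896 genes, against a median of 459 in the other splits. The 896 genes still lie below the 939.8 expected from the number of genes tested. The count thus exceeded most splits but not that expectation. The splits were not repeated without single libraries, where the unadjusted counts were 1413 to 2371 in males, 953 to 1762 in females, 2368 to 3208 for the average and 611 to 1019 for sex in controls. The female count was thus near the 934.9 expected by chance without Control.female 5, and the averaged count was 1721 with the decidual covariate. Chance was not excluded for the number of lists, for genes called in males and for the unadjusted counts of the interaction and of sex in obese embryos. The correlation was only 0.075 without HFD.male 2 and 0.103 with the decidual covariate. The 3 counts with a real value of 0 are reached by every split and decide nothing. Splits with 230 and 95 genes, several times the real 1 and 10, and with 129 where the real count was 0, point to a structure of the samples.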
